A study of Mus musculus with 4 samples.

How the data were processed

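Tregs were sorted as CD4+Foxp3+ cells from the spleen and tracheal lymph nodes of WT and Csnk2b-deficient mice, and 4 libraries were sequenced on a MiSeq, per the labels. The labels' protocols give Trizol and the TruSeq RNA v2 kit for samples 1 and 2, and the RNeasy micro kit, the SMARTer cDNA kit and Nextera XT for samples 3 and 4, without saying which libraries these numbers name. They were taken in the order of listing, which makes samples 1 and 2 the spleen libraries (replicate 1 of each genotype) and samples 3 and 4 the lymph node libraries (replicate 2). The kits of each library rest on that assumption, and the tissues do not. CASAVA 1.8.2 and the genome build mm9 are named in the submitters' processing notes. The aligner and the annotation are not given in the sources used here.

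The deposited tables list counts of reads per gene (exon reads, gene reads, and each as unique and total reads), per the file headers, with the chromosome, start and end of each gene. The authors also gave RPKM, which equalled total exon reads per kilobase of exon, scaled by total gene reads, within 0.0005 for genes with over 500 exon reads, and this RPKM was not tested. Of 37583 listed features, 9551 had no exon length and 0 exon reads and were left out, and 28032 remained. No mitochondrial gene was among them. Total exon reads, which include reads with more than 1 placement, were taken as the counts because the authors' RPKM rests on them. That choice was made after the tables were opened and before any fit, and uniquely placed exon reads were run as an alternative. Between 78.3% and 86.2% of exon reads were uniquely placed. Whether the counting used strand is not given in the sources used here, so overlapping genes, antisense genes and paralogs are uncertain.

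Libraries of 1 pair were compared for duplication: their read counts differed by a chi-square of 7.96 per degree of freedom in the spleen and 31.5 in the lymph node, well beyond sampling noise. Pearson correlations of log2 CPM over genes were 0.978 within the spleen pair, 0.899 within the lymph node pair and 0.723 to 0.751 across tissues. The labels give the tissue of each library, the spleen for replicate 1 and the tracheal lymph nodes for replicate 2 of both genotypes, so the numbers pair the libraries by tissue. Deviations from the genotype means correlated at 0.783 within a number.

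Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by genotype, TMM factors, robust dispersion and the quasi-likelihood test on tissue plus genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. The tissue term served as the block, leaving 1 residual degree of freedom, with the spread moderated across genes (prior degrees of freedom 10.1, biological coefficient of variation 30.0%). That degree of freedom is the difference of the genotype change between the tissues, so the coefficient is not a spread between like libraries. A fit without the block was the alternative. It called 0 genes by edgeR, with 29 at an unadjusted p below 0.05. SEs are the log2 fold change over the square root of its F statistic. Ratios within a pair are differences of log2 CPM with a prior count of 2. The difference between tissues is the tissue coefficient of the same fit.

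The 34 gene lists, the tests of the comparisons in the report, the alternative settings other than uniquely placed reads and the rule for named genes were fixed before the data were examined. The choice of the count column, the alternative of uniquely placed reads and most tests of explanations were made later. The rule took Csnk2b and the catalytic subunits, and Foxp3 and Lilrb4 with its paralog. It took the 12 genes that rose most and the 12 that fell most among those past the threshold, with the same direction in both pairs and at least 5 CPM, filled to 12 by the smallest unadjusted p. It also took up to 4 members of each list by the smaller of their changes in the pairs, and 5 genes per direction for the tissue difference. Lists with at least 3 measured genes, 32 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each Benjamini-Hochberg adjusted over the lists. Camera at an estimated correlation and fry rest on the 1 residual degree of freedom of the fit, so they had little power to call a list. Within each pair the median of a list was ranked among 10000 random lists matched on expression in 20 bins. The random lists were drawn gene by gene, so these ranks do not allow for genes that vary together. The mitochondrially encoded list had 0 members and the erythroid and platelet list had 2 measured members, so neither was tested.

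Alternatives were size factors by the median of ratios, upper-quartile scaling, no filter except 0 reads, a filter at 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, and fits without the block or without single libraries. A single pair leaves no residual degrees of freedom, so its log2 ratio is a value with no test. GC content came from the transcripts of another mouse build matched by gene symbol, for 89.4% of tested genes, and no coordinates were taken from that build. Figures were drawn with matplotlib 3.10.9.

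The fit was tested on simulated counts for the genotype comparison, with 11113 genes and 200 changed genes in each of 5 runs. It recovered 89.2% of genes raised 4-fold, 58.8% of genes lowered 4-fold, 35.6% of genes raised 2-fold and 24.4% of genes lowered 2-fold. It called 6.4 unchanged genes per run on average. Genes were drawn independently of each other, and the changed ones had a mean of at least 5 CPM. The genes of a shifted list were raised in the same runs. So many changed genes ease the adjusted threshold, so the shares recovered may overstate the power in the data. At an unadjusted p below 0.05, camera with the preset correlation called a shifted list in 5 of 5 runs and an unshifted list in 0. These runs cannot tell how often it calls an unshifted list whose genes vary together, so they do not decide on the lists called in the data. Estimated correlations of those lists lay on both sides of the preset one, such as 0.17 for effector Treg, 0.22 for cell cycle and -0.055 for Th1 genes.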

Results

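Messenger RNAs of CD4+Foxp3+ regulatory T cells (Tregs) were counted in 4 libraries from C57BL/6 mice aged 8 weeks. Tregs are the CD4 T cells that restrain other immune cells, and Foxp3 is their lineage-defining transcription factor. The cells were sorted by flow cytometry from wild-type (WT) mice and from mice deficient in Csnk2b, the regulatory beta subunit of protein kinase CK2, with 2 libraries per genotype. Replicate 1 of each genotype was Tregs of the spleen, and replicate 2 was Tregs of the tracheal lymph nodes, which drain the airways. Total exon reads were 6750695 in WT replicate 1, 4877882 in Csnk2b-deficient replicate 1, 4737814 in WT replicate 2 and 5506113 in Csnk2b-deficient replicate 2. Genes with at least 1 exon read numbered 15515 and 14962 in the spleen libraries, and 12157 in WT and 14335 in Csnk2b-deficient lymph node Tregs. The labels do not say whether the libraries came from single animals or pools. Each genotype and tissue had 1 library, so n = 2 per genotype counts 1 library of each tissue. The p-values and SEs rest on how far the genotype change differed between the tissues, moderated across genes, and not on replicate libraries or animals.

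Csnk2b, the targeted gene on chromosome 17 (35253141 to 35258998, mm9), had fewer reads in both Csnk2b-deficient libraries. In the spleen it had 148 exon reads, or 25.6 CPM (read counts scaled to library size), compared with 649 reads, or 82.3 CPM, in WT. In the lymph node it had 283 reads (62.0 CPM) compared with 667 reads (163 CPM) in WT. The log2 fold change was -1.54 ± 0.26 (SE, n = 2 per genotype), with -1.67 in the spleen pair and -1.39 in the lymph node pair. Its adjusted p of 0.0658 missed the threshold of 0.05, and it ranged from 4.99e-05 to 1.00 over 12 alternative fits. The genes of the catalytic subunits, Csnk2a1 and Csnk2a2, had log2 fold changes of -0.17 ± 0.22 and -0.41 ± 0.40 (adjusted p = 0.932 and 0.895). Both had pair ratios near 0 in the spleen, 0.01 for Csnk2a1 and 0.03 for Csnk2a2, and lower values in the lymph node, -0.35 and -0.87.

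The comparison of Csnk2b-deficient with WT Tregs asked which transcripts depended on the beta subunit. Lilrb4, which encodes the inhibitory receptor ILT3, rose from 14.5 to 170 CPM in the spleen and from 9.78 to 351 CPM in the lymph node (log2 fold change 4.29 ± 0.37, SE, n = 2 per genotype, adjusted p = 0.00225). Of receptor genes, Il1rl1, the interleukin-33 receptor, rose by 2.24 ± 0.36 on the log2 scale, with 1.57 in the spleen and 3.00 in the lymph node. Its adjusted p of 0.0468 was lost with size factors by the median of ratios, upper-quartile scaling, a filter at 5 CPM and uniquely placed reads. Il18rap and Il18r1, the chains of the interleukin-18 receptor, rose by 2.22 ± 0.29 and 1.84 ± 0.22, and the decoy receptor Il1r2 by 2.04 ± 0.22. Gpr15, a homing receptor for the large intestine, rose by 2.63 ± 0.27, and Itgae, the CD103 integrin chain that binds E-cadherin on epithelium, rose by 2.24 ± 0.21. Foxp3 fell by 1.66 ± 0.25 (adjusted p = 0.0375), with a log2 ratio of -1.12 in the spleen and -2.21 in the lymph node. On uniquely placed reads its change was -0.71 ± 0.22 and was not called. Sesn1, a stress-induced FOXO target, fell by 1.72 ± 0.23 (adjusted p = 0.0124). Il18rap, Foxp3 and Sesn1 lost their calls with size factors by the median of ratios and with uniquely placed reads. Il18r1 lost its call with those size factors, and Foxp3 also with upper-quartile scaling.

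Of 11113 genes tested, 14 were higher and 2 lower in Csnk2b-deficient Tregs at an adjusted p below 0.05. All 16 had the same direction in both pairs. The test sets the joint genotype change against the difference between the pairs, moderated across genes, so it favours genes whose pairs agree. That shared direction is thus no separate support. The fold change of 1 pair alone differed over 1.5 times from the joint one for Lilrb4 (log2 3.52 in the spleen and 5.11 in the lymph node), Gp49a (3.81 and 5.92), Ttn (2.12 and 3.62) and Il1rl1. The other genes that rose were Gp49a (log2 fold change 5.51 ± 0.88, SE, n = 2 per genotype), Ttn (2.85 ± 0.33), which encodes the muscle protein titin, Bzrap1 (2.58 ± 0.30), Penk (1.65 ± 0.20), which encodes the enkephalin precursor, and Id2 (1.56 ± 0.24), an inhibitor of E-protein transcription factors. Casp1, the inflammasome caspase, rose by 1.55 ± 0.24 and Cldn25 by 1.41 ± 0.19. These last genes fell outside the rule for named genes and were chosen after their values were seen. With size factors by the median of ratios, Gp49a, Ttn, Bzrap1, Penk, Id2, Casp1 and Cldn25 lost their calls. Gp49a, Id2 and Casp1 also lost them with upper-quartile scaling and with uniquely placed reads, and Cldn25 with uniquely placed reads. Gp49a was lost as well with a filter at 5 CPM and with limma-voom. Of Ttn reads 62.2% were uniquely placed, and on these its log2 fold change was 2.56 with an adjusted p of 0.0626. At an unadjusted p below 0.05 there were 542 genes, compared with 556 that chance gives. Size factors by the median of ratios called 4 higher and 0 lower, uniquely placed reads called 7 higher and 0 lower, and edgeR without the tissue term called 0, with 29 at an unadjusted p below 0.05. The DESeq2 Wald test called 38 higher and 16 lower, limma-voom 39 and 21, and edgeR without a filter 79 and 32.

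**Figure D1:**
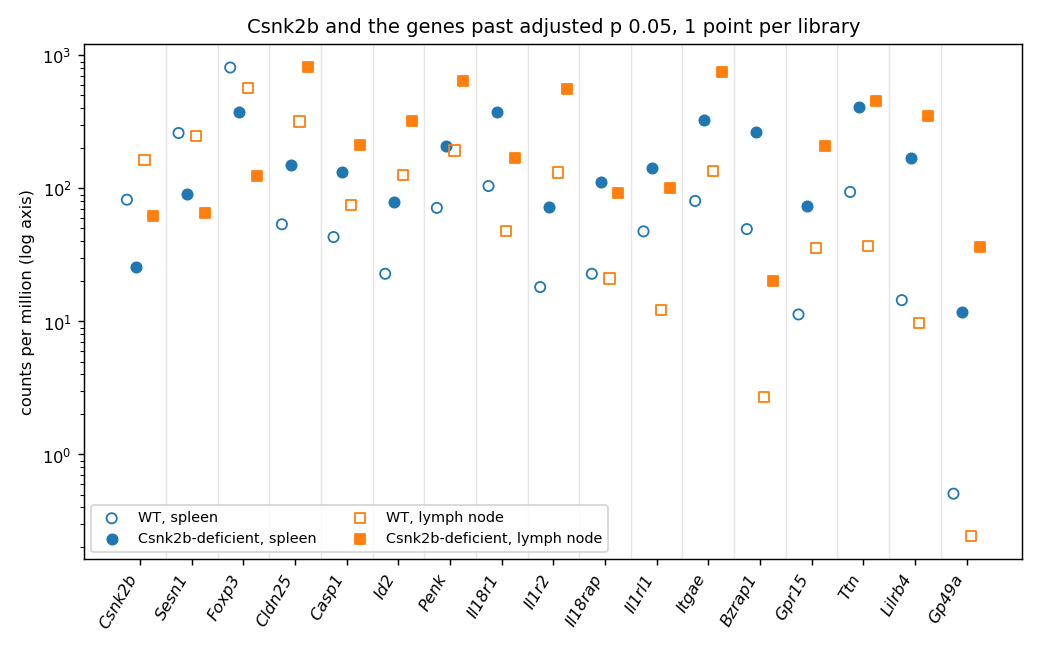
CPM on a log axis for Csnk2b and the 16 genes past an adjusted p of 0.05, with 1 point per library, open symbols for WT and filled symbols for Csnk2b-deficient Tregs, circles for spleen and squares for lymph node. In each of the 14 genes that rose, the filled symbol lies above the open symbol of its tissue, and for Csnk2b, Sesn1 and Foxp3 it lies below.

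Foxp3 and Lilrb4 share sequence with other annotated features, which limits their counts. The span of Foxp3 on chromosome X (7156802 to 7172369, mm9) lies inside the listed span of Ppp1r3f (7134422 to 7182507), and 25.9% of Foxp3 exon reads were placed uniquely. That share differed by genotype, with 25.5% in WT and 35.8% in Csnk2b-deficient spleen Tregs, and 14.6% and 39.0% in the lymph node. Uniquely placed Foxp3 exon reads numbered 1633 and 773 in the spleen, and 340 and 219 in the lymph node. On uniquely placed reads the Foxp3 change was -0.71 ± 0.22 with an adjusted p of 0.90, and the call was lost. Gp49a on chromosome 10 (51200438 to 51206122) overlaps its paralog Lilrb4 (51200446 to 51216419), so the Gp49a change is uncertain, and it rested on 4 and 1 reads in WT compared with 68 and 165. On uniquely placed reads Lilrb4 remained called at 4.21 on the log2 scale, with an adjusted p of 0.0247.

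In the downward direction edgeR called 2 genes. The rule then took the 10 genes of smallest unadjusted p among those lower in both pairs with at least 5 CPM. They did not pass the threshold, and being lower in both pairs was a condition of entry. Of these 10, DESeq2 called 9, all but Ifit3, limma-voom called 9, all but Gm9825, and edgeR without a filter called 10. These fits of the same libraries called 54, 60 and 111 genes in all, compared with 16. The 10 genes were picked by their p in the same counts, so such calls are no separate support. Besides Csnk2b the 10 genes included the naive-cell marker Ly6c1 (log2 fold change -1.62 ± 0.29, SE, n = 2 per genotype, adjusted p = 0.0786) and Bach2 (-1.56 ± 0.30, adjusted p = 0.119), a transcription factor that restrains effector differentiation. Il6ra and Il6st, the chains of the interleukin-6 receptor, had values of -1.42 ± 0.28 and -1.14 ± 0.21 (adjusted p = 0.134 and 0.108). Tlr7, a sensor of single-stranded RNA, had -2.49 ± 0.48, and Ugcg, which makes glucosylceramide, had -1.36 ± 0.27. The interferon-induced genes Usp18 and Ifit3 had -1.16 ± 0.23 and -1.56 ± 0.33. Gm9825 had 84 and 78 reads in WT compared with 1 and 0, with an edgeR adjusted p of 0.107 and 37.4% of its reads uniquely placed. With reads pooled over the tissues the ratio was 140, with a 95% exact binomial interval of 24.8 to 5560. That interval covers counting error only and not the spread between libraries.

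Genes of effector Tregs had a median log2 fold change of 0.65, and the camera test placed the list above the other genes with a preset correlation of 0.01 (adjusted p = 2.09e-16) and did not call it with an estimated correlation (adjusted p = 0.639 with an estimated correlation). Of 29 measured members of this list, 22 were higher in both pairs and 3 lower in both. Over all genes edgeR called 2 higher, Itgae and Il1rl1, while DESeq2 and limma-voom, which called more genes in all, each called 7. With p adjusted over the list alone 12 rose in edgeR. The aryl hydrocarbon receptor gene Ahr had a log2 fold change of 1.90 ± 0.33, Fgl2, which encodes a suppressive secreted protein, 2.10 ± 0.73 with 7.87% of its reads uniquely placed, the protease Gzmb 2.76 ± 0.67, and the receptor Klrg1 0.99 ± 0.26 (SE, n = 2 per genotype). In spleen and lymph node Gzmb had log2 ratios of 1.29 and 4.39, and Klrg1 0.61 and 1.37. The median was 0.43 in the spleen pair and 1.12 in the lymph node pair, each above 100% of 10000 random lists matched on expression. Those lists were drawn gene by gene and do not allow for genes that vary together. The estimated correlation of this list was 0.17. The lymph node pair includes the WT library with reads in 12157 genes, the fewest of the 4.

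The camera test called 14 of 32 lists with the preset correlation, 9 higher and 5 lower, and called 0 with an estimated correlation, where 0 lists had an unadjusted p below 0.05. Fry called 0 lists, with 2 at an unadjusted p below 0.05. Camera with an estimated correlation and fry both rest on 1 residual degree of freedom. The Th1 list had an estimated correlation of -0.055, below the preset one, and its unadjusted camera p still went from 8.35e-07 to 0.12. The counts of 0 thus argue neither for nor against a list. Of 14 Th1 genes, 2 rose over all genes, Il18rap and Il18r1, and 3 with p adjusted over the list alone, the third being the chemokine receptor Cxcr3 (1.30 ± 0.31, with 0.60 in the spleen and 1.99 in the lymph node). Il12rb2, a Th1 receptor chain, was lower in both pairs at -1.16 ± 1.21. The list had an adjusted p of 8.91e-06, and adjusted p = 0.639 with an estimated correlation. Among 16 inhibitory receptors and ligands, 2 rose over all genes, Lilrb4 and Gp49a, which overlap and share reads. With p adjusted over the list alone 5 rose, including Klrg1 and Cd200r1 (0.73 ± 0.25). In both pairs 8 members were higher and 4 lower, and the median log2 fold change was 0.33 compared with a mean of 0.87. That list had an adjusted p of 1.14e-05, and adjusted p = 0.639 with an estimated correlation.

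Of 17 genes in the cytokine list, 1 rose over all genes, Penk, the enkephalin precursor gene, which is not a cytokine gene. With p adjusted over the list alone 3 rose, Penk, Tnfsf8 and Ebi3, the interleukin-35 subunit (1.41 ± 0.38). Tnfsf8, the CD30 ligand at 1.12 ± 0.24, was chosen after its values were seen. Il4 had 6 and 7 reads in WT and 23 and 61 in Csnk2b-deficient Tregs, with a log2 fold change of 2.66 ± 1.09, and Tnfsf14 had 1.28 ± 0.55. The cytokine list had an adjusted p of 6.13e-05, and adjusted p = 0.639 with an estimated correlation. Of 12 Th2 genes, 1 rose over all genes, Il1rl1, and 2 with p adjusted over the list alone, Il1rl1 and the hypoxia-inducible factor gene Epas1 (4.26 ± 1.22, with 11 and 0 reads in WT compared with 87 and 30). The Th2 list had an adjusted p of 0.00908, and adjusted p = 0.644 with an estimated correlation. Its median was 0.26 in the spleen pair and 0.11 in the lymph node pair, above 99.9% and 63.1% of the random lists matched on expression. Of 20 chemokine receptor and homing genes, 2 rose over all genes, Gpr15 and Itgae, and with p adjusted over the list alone 4 rose, including Ccr2 (1.35 ± 0.29), and 2 fell. Gpr183 had 2.13 ± 1.05. This list had an adjusted p of 0.00185, and adjusted p = 0.639 with an estimated correlation. In both pairs 8 members were higher and 6 lower. Its median was 0.058 in the spleen pair and 0.0030 in the lymph node pair, above 93.3% and 44.1% of the random lists.

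The cell cycle list had a median log2 fold change of 0.51 and was called higher with the preset correlation (adjusted p = 7.09e-05) and not otherwise (adjusted p = 0.689 with an estimated correlation). Of 39 measured members 22 were higher and 4 lower in both pairs. Of these 39, edgeR, DESeq2 and limma-voom each called 0 over all genes, with 3, 4 and 5 at an unadjusted p below 0.05, edgeR called 0 with p adjusted over the list alone, and the median was 0.16 in the spleen and 0.88 in the lymph node, whose WT library had reads in 12157 genes, the fewest of the 4. Birc5 had a log2 fold change of 1.46 ± 0.61, Bub1 3.06 ± 1.62, Cdk1 0.90 ± 0.73 and Ube2c 1.62 ± 1.21, all from low counts. Bub1 had 18 and 23 reads in the spleen and 0 and 69 in the lymph node (WT and Csnk2b-deficient), with log2 ratios of 0.72 and 5.43.

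The type I interferon response list had a median log2 fold change of -0.48 and was called lower with the preset correlation (adjusted p = 3.29e-06) and not otherwise (adjusted p = 0.689 with an estimated correlation). Of 26 measured members 19 were lower and 2 higher in both pairs. The median was -0.19 in the spleen and -0.73 in the lymph node, whose WT library had reads in the fewest genes, 12157. Over all genes edgeR called 0, with 5 at an unadjusted p below 0.05, DESeq2 called 2 lower and limma-voom 3 lower, and 3 fell in edgeR with p adjusted over the list alone: Usp18, Ifit3 and Ifit1. Ifit1, chosen after its values were seen, had -1.58 ± 0.42, with -0.50 in the spleen and -2.50 in the lymph node, the antiviral synthetase gene Oas2 had -2.50 ± 0.82 and Oasl1 had -1.55 ± 0.99 (SE, n = 2 per genotype).

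Of 18 genes of naive and central T cells, edgeR called 0 over all genes, with 9 at an unadjusted p below 0.05, while DESeq2 called 1 higher and 3 lower and limma-voom 1 higher and 2 lower. With p adjusted over the list alone 6 fell and 1 rose. Ly6c1 and Bach2 were among those that fell. Il7r, the interleukin-7 receptor, rose by that count at 1.05 ± 0.22. The naive list had an adjusted p of 0.000865, and adjusted p = 0.639 with an estimated correlation. Of 17 FOXO target genes, 1 fell over all genes, Sesn1, and with p adjusted over the list alone 2 fell, including Sesn1, and 1 rose, Il7r. Bcl2l11, which promotes apoptosis, had -0.70 ± 0.32 and Pik3ip1 -0.65 ± 0.32. The FOXO list had an adjusted p of 0.00185, and adjusted p = 0.639 with an estimated correlation. Of 80 cytosolic ribosomal protein genes edgeR called 0 by either count, with 6 at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 over all genes. Of the 80, 47 were lower in both pairs, and the median was -0.18, with Rpl27a at -0.50 ± 0.20 and 13.1% of its reads uniquely placed (list adjusted p = 4.67e-05, and adjusted p = 0.689 with an estimated correlation). The list of 3 CK2 subunits was lower with an adjusted p of 0.00134, and adjusted p = 0.639 with an estimated correlation, and its only member past p adjusted over the list alone was Csnk2b.

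The core signature of Tregs moved in both directions. Of 29 measured members, 2 rose, Itgae and Penk, and 1 fell, Foxp3, over all genes. With p adjusted over the list alone 3 rose and 3 fell, the additional genes including Rgs1 (0.79 ± 0.17) and Plagl1 (-1.56 ± 0.49, with -0.95 in the spleen and -2.13 in the lymph node). Rgs1 was chosen after its values were seen. The list had a median log2 fold change of 0.00, a mean of -0.03 and an adjusted p of 0.763, with the camera direction up. The other lists that were not called had adjusted p from 0.135 for cholesterol synthesis to 0.994 for p53 targets and apoptosis. Among 20 IL-2 and STAT5 targets 1 fell over all genes, Foxp3, and the list had an adjusted p of 0.157.

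Markers of other cell types were measured beside these groups, since a sort can carry such cells. The myeloid and dendritic cell list had 6 measured members and was higher with an adjusted p of 0.00185, and adjusted p = 0.639 with an estimated correlation. Lyz2, the macrophage lysozyme, had 20 and 19 reads in the spleen pair and 187 and 1291 in the lymph node pair, and Cd68 had 28 and 23, and 0 and 63 reads. The B cell list of 12 genes was higher with an adjusted p of 0.0341, and adjusted p = 0.689 with an estimated correlation. Its members Cd74, the invariant chain of MHC class II (1.22 ± 0.22), H2-Eb1 (2.63 ± 0.71) and Igkc (1.91 ± 0.50, with 0.40 in the spleen and 2.70 in the lymph node, chosen after its values were seen) passed with p adjusted over the list alone. The list of 8 CD8 T and NK cell genes had an adjusted p of 0.195, that of 4 plasma cell genes 0.289, that of 16 general T cell genes 0.874 and that of 4 stromal and endothelial genes 0.692.

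**Figure D2:**
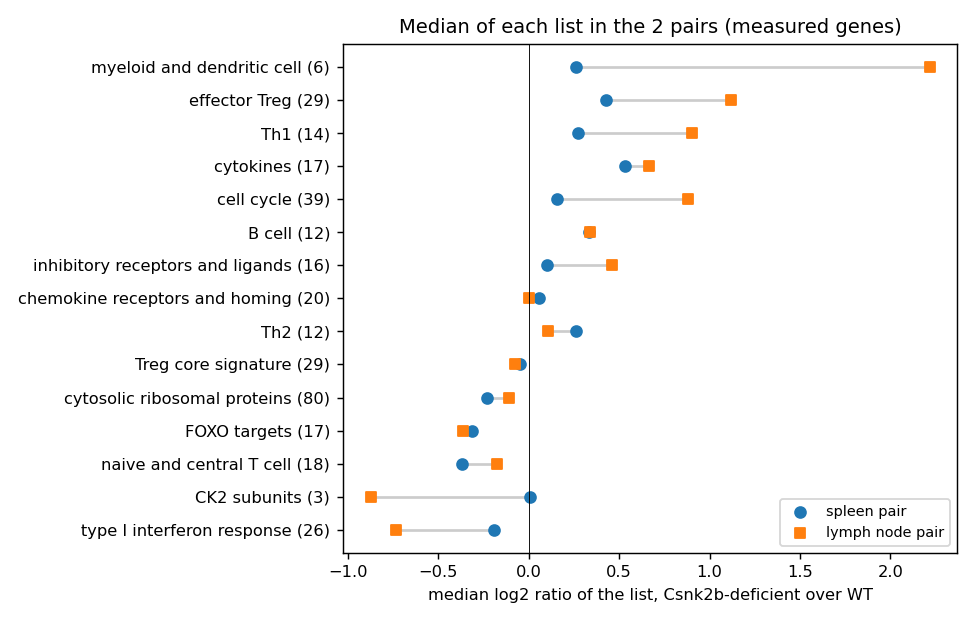
Median log2 ratio of Csnk2b-deficient over WT in the spleen pair (circles) and the lymph node pair (squares) for the 14 lists that the camera test called and for the Treg core signature, with the number of measured genes in brackets. The effector Treg list lies at 0.43 and 1.12 and the type I interferon list at -0.19 and -0.73.

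Each pair is a separate contrast of the genotypes, so the spleen ratio of a gene was set against its lymph node ratio. Lilrb4 had log2 ratios of 3.52 and 5.11, Gpr15 2.68 and 2.54, Il18r1 1.85 and 1.83, and Sesn1 -1.52 and -1.92 in spleen and lymph node. The genotype test favours genes whose pairs agree, so these called genes do not measure the agreement. Over the 11113 genes the correlation across genes was 0.243 (Pearson) and 0.20 (Spearman), and 56.9% had the same sign in both pairs. Genes are not independent replicates, so no p is given. Of the 200 genes with at least 5 CPM most raised in the spleen, 147 were higher in the lymph node, or 73.5% compared with 50.2% of all such genes, and of the 200 most lowered 141 were lower, or 70.5%. Ratios spread more in the lymph node pair, with an SD over genes of 1.18 compared with 0.44 in the spleen. With 1 library per genotype and tissue, a difference of the genotype change between the tissues was not tested.

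**Figure D3:**
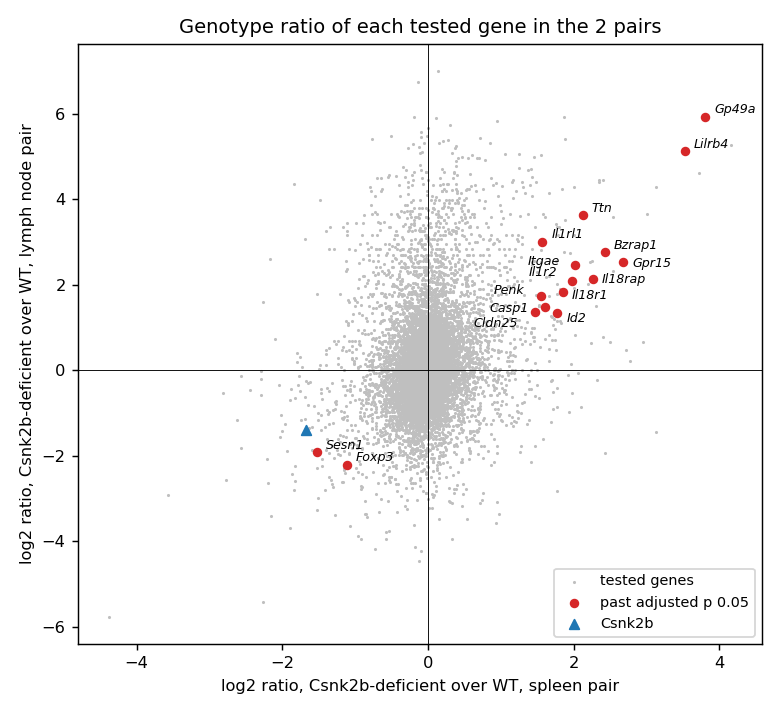
Log2 ratio of Csnk2b-deficient over WT in the spleen pair (horizontal axis) and in the lymph node pair (vertical axis), with 1 point per tested gene, red points for the 16 genes past an adjusted p of 0.05 and a blue triangle for Csnk2b. The red points lie in the upper right and lower left, with Lilrb4 at 3.52 and 5.11. The test favours genes whose pairs agree, so this placement is no separate support.

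Lymph node libraries differed from spleen libraries in 5050 of 11113 genes (45.4%), 2586 higher and 2464 lower. With the protocol's sample numbers taken in the order of listing, the tissue, the RNA extraction and the library kit changed together, so only their joint difference was measured. Pld4, an endolysosomal nuclease, had 2 and 0 reads in the spleen and 83 and 42 in the lymph node, a ratio of 98.7 with a 95% exact binomial interval of 26.8 to 824. Pla2g2d, a secreted phospholipase, had 1 and 1 reads compared with 29 and 105, a ratio of 106 (interval 28.7 to 883), and Lyz1 had 0 and 2 compared with 15 and 103, a ratio of 93.2 (25.2 to 778). Phxr4 had 1 and 0 reads compared with 65 and 55, and Gm9846 had 14.5 CPM in both spleen libraries compared with 909 and 1438 CPM (log2 change 6.29 ± 0.26), with 0.821% of its reads uniquely placed.

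Ano8, Il3ra, Egr3, Zfp498 and Cdh24 had 0 reads in both lymph node libraries. Compared with a floor of 3 counts per library they were at least 36.1-fold, 29.5-fold, 27.1-fold, 26.8-fold and 18.2-fold lower there. Il3ra is the interleukin-3 receptor chain and Egr3 a factor induced by T cell receptor signals. The intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Upper-quartile scaling moved the median change of all genes by -0.15 on the log2 scale and turned the balance to 2293 higher and 2785 lower. Across the 9933 genes with a known GC content, the change had a Spearman correlation of -0.37 with GC content, and the median change went from 0.36 in the lowest of 5 equal GC groups to -1.61 in the highest. Without the genotype term and without WT replicate 1 the count of genes was 2186, without Csnk2b-deficient replicate 1 it was 2322, and without Csnk2b-deficient replicate 2 it was 7874.

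**Figure D4:**
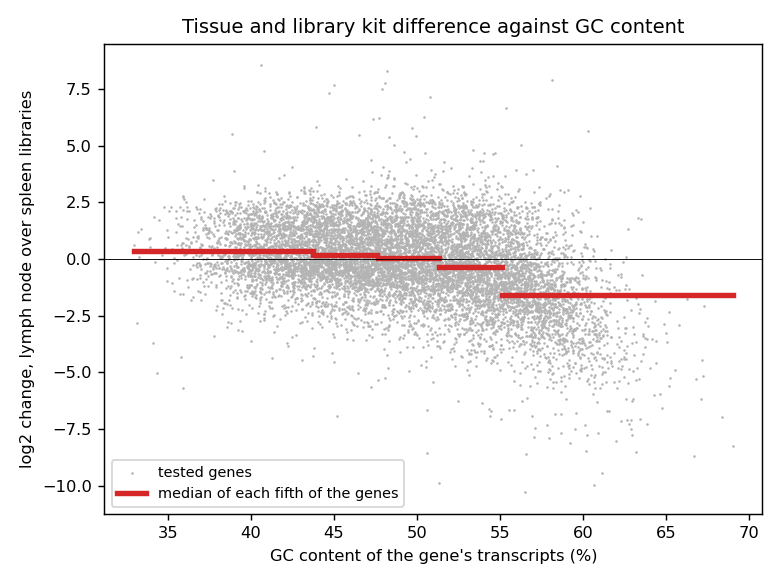
Log2 change of lymph node over spleen libraries (vertical axis) against the GC content of each gene's transcripts in percent (horizontal axis), with 1 grey point per tested gene of known GC content and red bars for the medians of 5 equal groups of genes by GC content. The bars step down from 0.36 at the lowest GC content to -1.61 at the highest.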

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

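The tests on Foxp3, on Lilrb4 and on the GC correlation were chosen after their results were seen, and the test by GC and length correction was chosen before its result was known.

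Foxp3 exon reads fell in both pairs, by 1.66 ± 0.25 on the log2 scale (SE, n = 2 per genotype). The sum of all reads of the 4 overlapping features, which includes those of Foxp3, had a change of -0.87 ± 0.21 (edgeR unadjusted p = 0.00158, adjusted p = 0.293). That argues against reads only moving between these features as the whole cause. It cannot tell which feature the shared reads came from, so sharing with Ppp1r3f is not decided by the sum. Uniquely placed exon reads of Foxp3 changed by -0.71 ± 0.22, so sharing may account for part of the size. For fewer Tregs among the sorted cells, the 28 other core Treg genes had a median change of 0.0072 and a lower quartile of -0.31. Of these genes 0 fell as far as Foxp3 and 3 as far as its uniquely placed reads. They did not fall as a set, but how far each is particular to Tregs was not measured, and Itgae and Penk rose. The values thus do not decide on this cause. A lower transcript level of Foxp3 in Csnk2b-deficient Tregs stays open as a hypothesis, as does the makeup of the mouse alleles, which was not tested. Foxp3 reads outside exons had a log2 change of 0.37 ± 0.22 when edgeR was fitted on such reads (unadjusted p = 0.12). In each library the uniquely placed gene reads of Foxp3 equalled its uniquely placed exon reads, so its reads outside exons were not uniquely placed. The span lies inside that of Ppp1r3f, so this value does not show how Foxp3 itself changed outside exons.

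Lilrb4 rose in both pairs, and reads shared with Gp49a are argued against by the change of 4.21 on uniquely placed reads. For myeloid cells, which also express Lilrb4 and which the sort for CD4+Foxp3+ cells would remove, a first form of the test summed 28 myeloid and dendritic cell genes and gave log2 ratios of 0.16 in the spleen and 0.44 in the lymph node, and after those values were seen Ctss, which made up 90.0% and 93.2% of the WT sums, was left out and each pair was judged apart. In the spleen pair the summed reads of the other 27 myeloid and dendritic cell genes had a log2 ratio of -0.17 (95% counting interval -0.53 to 0.18) compared with 3.52 for Lilrb4, which argues against such cells there. In the lymph node pair that sum had a ratio of 2.33 (2.16 to 2.51) compared with 5.11 for Lilrb4, led by Lyz2 with 1291 reads while Tyrobp had 25 and Fcer1g 26. A share of the lymph node rise from myeloid cells cannot be told apart from a rise in Tregs, because 18 of the 20 summed markers with reads in that pair were higher, with Lyz2 as 75.1% of the Csnk2b-deficient sum, and 2 were lower, C1qc with 20 and 3 reads and Fcgr2b with 21 and 7.

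Lymph node libraries differed from spleen libraries in 5050 genes, and the GC content of a gene had a Spearman correlation of -0.37 with its change, so base composition read differently by the library kits may be part of the cause. As the whole cause, composition and length are argued against by a loess correction for both, after which 64.6% of the 4481 called genes with a known GC content were still called with the same sign. That correction lowered the count of called genes from 4481 to 3586, with 2292 higher and 1294 lower. Tissue, extraction and kit remain joined by the design, and a biological difference between spleen and lymph node Tregs was not tested apart from them.

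The pairs had medians of opposite sign in 8 lists, and the difference between tissues was not tested. The lymph node median minus the spleen median was -0.88 for CK2 subunits, 0.43 for Tfh and Tfr genes, 0.36 for glycolysis and hypoxia, 0.11 for the unfolded protein response, 0.091 for immediate early genes, 0.23 for general T cell genes, 0.93 for 4 histone genes and 0.12 for oxidative phosphorylation. For Csnk2a1 the ratio differed by -0.36 and for Csnk2a2 by -0.90, again without a test.

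Reads outside exons of the same libraries were not part of the gene test. Of 15 called genes that could be fitted on such reads, 14 had the direction of their exon reads, compared with 60.2% of 8887 genes not called. The exception was Foxp3, with 1387 and 1562 reads in the spleen and 130 and 179 in the lymph node (WT and Csnk2b-deficient). Lilrb4 had 289 and 2858, and 5 and 2293 such reads. Those of Foxp3 were not uniquely placed in any library, so they may belong to other features. The called genes were picked by their exon reads, so this count is no separate test of the genotype. Over 9739 genes edgeR called 0, with 291 at an unadjusted p below 0.05, fewer than the 487 that chance gives, and no other tool was run on these reads.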

How the results depend on the processing

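All alternatives were planned except the count of uniquely placed exon reads, which was chosen after seeing the data. The number of genes called by genotype was not stable. Size factors by the median of ratios called 4 genes, 4 higher and 0 lower, all among the 16, and upper-quartile scaling called 11, with 10 higher and 1 lower. Testing without a filter called 111, 79 higher and 32 lower, the DESeq2 Wald test 54 (38 and 16), limma-voom 60 (39 and 21), and uniquely placed reads 7 (7 and 0). DESeq2 kept all 16 genes and limma-voom 15. The fit with no replicate block called 0, 0 higher and 0 lower, with 29 genes at an unadjusted p below 0.05. Without the block and without single libraries the count went from 0 to 1, with 0 to 1 higher and 0 lower. These fits confound the tissue with the genotype by construction, and the causes of the other shifts were not tested. The 16 genes, picked from the same libraries, kept their direction in every fit with all 4 libraries. Their values moved by more than the spread for 5 of the 16 without replicate 1 and 6 without replicate 2.

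Csnk2b had an adjusted p below 0.05 at -1.54 without a filter, -1.53 by DESeq2 and -1.52 by limma-voom, and missed it in the other fits. The tissue difference went from 2186 to 7874 genes over the fits without single libraries and without a genotype term, 1255 to 3698 higher and 931 to 4295 lower. The other fits called 4601 to 5616 genes. The correlation between pairs was 0.389 for genes above 50 CPM. With an estimated correlation 0 lists were called, and 0 by fry, on 1 residual degree of freedom, which leaves these tests little power. Members above 5 CPM, uniquely placed reads and the fit without the block called 14 lists each, 13 of them shared in the last, where the B cell list was lost and the CD8 T and NK cell list was gained.

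Ppp1r3f, at -0.38, reversed to 0.63 on uniquely placed reads, and the cause was not tested. In the spleen pair alone, a value with no test, Csnk2a1 was 0.01 and Csnk2a2 0.03, above 0 in place of below. The other changes of sign among the named genes came in fits without the block and without 1 library, where the tissue enters the genotype change. Over the leave-one-out settings the log2 change ranged from -0.40 to 5.76 for Bzrap1, -0.27 to 3.19 for Cldn25, -0.0038 to 4.15 for Il1r2, -0.76 to 0.35 for Csnk2a1, -0.95 to 0.12 for Csnk2a2, -0.23 to 2.84 for Cd74, -2.13 to 5.28 for Igkc, -2.26 to 9.14 for Lyz1, -2.81 to 5.84 for Lyz2, -1.09 to 2.75 for Rgs1, -3.42 to 0.74 for Ifit1, -3.01 to 0.13 for Ifit3, -3.74 to 1.49 for Usp18 and -0.75 to 0.030 for Ppp1r3f. Depth limits genes of few reads, such as Gp49a, Bub1 and Epas1.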

Other observations

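The genes described here lie outside the comparisons of the report and were chosen after their values were seen. Kynu, which encodes the kynurenine pathway enzyme kynureninase, had 0 reads in both WT libraries and 28 and 64 in Csnk2b-deficient Tregs, at least 6.61-fold higher compared with a floor of 3 counts per library, with an adjusted p of 0.232. Casp4, an inflammatory caspase gene next to Casp1 on chromosome 9, had 339 and 645 reads in the spleen and 27 and 812 in the lymph node (WT and Csnk2b-deficient, log2 fold change 2.83 ± 0.85, SE, adjusted p = 0.890). Foxo1, which encodes the transcription factor behind the FOXO target list, had a change of -0.90 ± 0.20 (adjusted p = 0.215), with 2543 and 989 reads in the spleen and 1569 and 944 in the lymph node.

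Several of the genes called by genotype are neighbours. Il1r2 (40141613 to 40182064), Il1rl1 (40486415 to 40522260), Il18r1 (40522397 to 40557699) and Il18rap (40572207 to 40608550) lie on chromosome 1 of mm9, Gpr15 and Cldn25 lie side by side on chromosome 16, and Gp49a overlaps Lilrb4 on chromosome 10. Chance placement of the called genes was tested after the pattern was seen: 8 of the 16 had another called gene within 0.5 Mb, compared with a mean of 0.268 and a maximum of 6 in 100000 random draws of 16 genes (permutation p = 1e-05, the smallest the draws can give). Without Gp49a, which shares reads with Lilrb4, 6 of 15 had such a neighbour, and 5 of 100000 draws of 15 genes gave as many (permutation p = 6e-05). Chance placement is argued against by both counts, and shared local control, a hypothesis, was not tested. Descent from a common ancestor gene, which the draws ignore, stays open for the interleukin-1 receptor family and for Lilrb4 and Gp49a, and shared reads stay open for that last pair. Uniquely placed reads made up 99.9% of Il1rl1 and 99.8% of Il18r1 exon reads.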
